A study of Mus musculus with 12 samples.

How the data were processed

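RNA was measured by total RNA sequencing of mouse hearts in 12 libraries, 3 in each of 4 groups: KO hearts with their own WT, and NS-DADm hearts with their own WT. Per the labels' protocols, RNA was extracted with TRIzol and a column kit, libraries were sequenced on an MGISEQ-2000 instrument to an average of 60 M reads (M, mega), and reads with adapters were removed with SOAPnuke 1.5.2. The submitters' processing notes name HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.12, DESeq2 1.4.5 and the genome build GRCm38.p6, without a role or order for any of them. Which of these tools made which value, and whether counting used strand, is not given in the sources used here. The labels number the replicates and call them biological, and do not say whether a number stands for an animal, litter or day.

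The authors deposited FPKM values per gene and library, per the file headers, as 1 table for each experiment. FPKM divides the fragments of a gene by its length and by the library's total, so a group of very abundant genes that rises lowers the values of all others. The tables were normalized separately, so each mutant was tested only within its own table. In the NS-DADm table between 1654 and 2212 genes per library had no listed value in the file deposited by the authors, and these were taken as 0. The authors' deposited tables also gave signed fold changes (the ratio where above 1, minus its inverse where below 1) and q-values of their own comparisons, for genes selected by the authors. These are quoted only as the authors' calls. A further 3 columns of per-sample values matched none of the samples and were not used.

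Of 17076 genes deposited for the KO experiment, 24 with a symbol turned into a date, 7 with a number for a symbol and 2 with a repeated symbol were left out, and 17043 were kept. Of 17857 for the NS-DADm experiment 24 were left out in the same way as dates and 17833 were kept. The 15471 genes in both tables were available for the test of the difference. Positions are from the annotation of GRCm38.p6, in which 19201 of 19405 symbols were found. Genes of families with near-identical copies, such as globins, metallothioneins, chemokines, MHC genes and olfactory receptors, are uncertain, because reads can be split between the copies.

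Depth was estimated from the low FPKM values, which rise in steps of whole fragments once a gene's length is taken into account. Between 63.5% and 77.3% of the 359 to 462 low values used per library fell within 0.15 of a whole number, where 30% would by chance and 41.0% to 42.0% did in simulated values without steps, as the best fit is picked. On simulated libraries of 9, 12, 20 and 40 M fragments the estimate was 9.0, 12.0, 19.9 to 20.0 and 40.1 M fragments (1807 genes of the KO and 2020 of the NS-DADm experiment). The estimate covers fragments in the listed genes and lies far below the reads stated in the labels. Not all values came out whole, so no counts were rebuilt, and no test on counts was run. The agreement of replicates was measured by a chi-square of the estimated fragments of each pair of libraries, over genes with 40 to 1000 fragments.

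The design fixed before the data were examined planned a count test for counts and limma for normalized values. As the values are FPKM, limma 3.58.1 was used in R 4.3.3, with moderated variances that follow the mean expression (trend) and are robust to outlying genes. It ran on log2(FPKM + 1), for genes of at least 1 FPKM in 3 or more libraries of the comparison. Fold changes from limma are on this scale, which understates the change of low genes, and folds quoted in the text are ratios of mean FPKM. A gene under 1 FPKM in every WT library was tested only through the mutant libraries, which fixes its direction. The p-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. KO was tested against its WT and NS-DADm against its WT, each in its own 6 libraries, and the difference of the effects in all 12 libraries with 4 group means. Overlaps were tested with one-sided Fisher's exact tests over the genes tested in both, and windows and chromosomes with Fisher's exact tests. Genes are not independent replicates in these tests.

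Before the data were examined, 35 gene lists and 20 lists of cell type markers were fixed. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over all lists of a comparison. The same was done with a correlation estimated from the data, and with fry, which asks whether the genes of a list move on balance one way. The rule for genes named in the text was fixed at the same time. It took the targeted genes with Hdac1 and Hdac2, then the 10 largest rises and the 10 largest falls by fitted log2 fold change among called genes. These needed a mean of at least 1 FPKM in the higher group, fully separate groups and a symbol other than that of a predicted gene, clone or LOC entry. It also took up to 4 members of a list with the smallest adjusted p and the members of a called list that moved against it, and the 5 largest positive and 5 largest negative differences of effect. Among genes called in both comparisons it took the 5 largest per pattern of directions by the smaller log2 fold change, and up to 3 members of each of the authors' themed sheets. Neighbours of Ncor1, sex-linked genes and single atrial markers named outside this rule were chosen after their values were seen. Some genes that the rule takes, and an alternative that leaves out regions around the targeted genes, are not reported here.

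The test was tested on simulated data made from the tables, with the observed spread of each gene and 50 genes changed at each fold. Only genes well above the 1 FPKM limit were changed, so the shares recovered do not cover genes near it. In the KO experiment (11320 genes) it recovered 92%, 98% and 100% of genes changed 1.5-fold, 2-fold and 4-fold, and in the NS-DADm experiment (11570 genes) 64%, 94% and 100%. At the smallest fold simulated, under 1.5-fold, it recovered 56% and 24%. It called 6 and 3 of the unchanged genes. Alternatives were centring on the library medians, no filter on low values, a pseudocount of 0.1, the replicate number as a block, a 2-fold minimum, all 12 libraries in one fit, the authors' deposited calls, and leaving out each library in turn. Alternatives chosen after seeing the data were the per-gene spread of the NS-DADm experiment for KO, each experiment's own spread for the difference, the mean of atrial markers as a covariate, and only the 3 libraries with low atrial markers. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for tables, Fisher's tests and figures.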

Results

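Total RNA of mouse hearts was sequenced in 12 libraries, which fall into 2 experiments of 6 libraries. In one experiment 3 libraries of hearts labelled as HDAC3 knockout (KO) were set against 3 of wild-type (WT) hearts. In the other, 3 libraries of hearts with the NS-DADm genotype were set against 3 WT libraries of their own. HDAC3 is a class I histone deacetylase that works inside nuclear corepressor complexes such as that built by NCOR1. NS-DADm hearts carry mutations in deacetylase-activating domains of such corepressors, and the labels describe their HDAC3 as inactive. The comparison of the genotypes asks which effects of HDAC3 on the adult heart depend on its enzyme activity. Expression was given as FPKM, and levels below are mean ± SD over the 3 libraries of a group (n = 3). The labels call the libraries biological replicates without naming animals, so every p-value measures the spread between these libraries, which may be technical.

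The FPKM of a library summed to between 605736.6 and 650460.5 in the KO experiment and to between 531362.2 and 560144.3 in the NS-DADm experiment. Between 11320 and 11699 genes reached 1 FPKM in a library. Low FPKM values rose in steps of whole fragments, from which the depth over the listed genes was estimated. It came to 8.8 to 8.9 M fragments (M, mega) in the WT and 10.2 to 10.8 M fragments in the KO libraries. In the other experiment it came to 10.2 to 11.3 M fragments in the WT and 12.4 to 12.8 M fragments in the NS-DADm libraries. Replicates of the KO experiment lay closer together than those of the NS-DADm experiment. Among genes with 40 to 1000 fragments, the mean chi-square per degree of freedom between pairs of replicates was 1.17 to 1.37 for KO and 1.26 to 1.37 for its WT. It was 4.94 to 5.73 for NS-DADm and 2.83 to 4.71 for its WT. Counting noise alone would give about 1, so in these genes the replicates of the KO experiment differed by little more than that. Such values cannot tell separate animals from repeat libraries of the same sample. All pairs of the KO experiment were alike in this, so no pair stood out to be merged. The n of 3 therefore follows the labels and was not shown by the data. The WT libraries of one experiment correlated with those of the other at 0.972 to 0.982 (log2 values, across genes). Each genotype was therefore set only against the WT libraries of its own experiment.

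Hdac3 itself (chromosome 18, 37936971 to 37955015, GRCm38.p6) was measured at 27.83, 29.45 and 27.12 FPKM in the WT hearts and at 8.51, 7.31 and 7.88 FPKM in the KO hearts. The fall from 28.1 ± 1.19 to 7.9 ± 0.6 FPKM (SD, n = 3) was 3.56-fold, a log2 fold change of -1.71 with a standard error of 0.0624 (limma adjusted p = 2.37e-09). Hdac3 RNA was thus lower but not absent in KO hearts. In the NS-DADm experiment Hdac3 was at 29.8 ± 2.02 in WT and 29.8 ± 0.804 in NS-DADm hearts (limma adjusted p = 0.975). Ncor1 (chromosome 11, 62315663 to 62457414) was at 22.9 ± 1.15 and 24.3 ± 1.01 FPKM in WT and NS-DADm hearts (limma adjusted p = 0.541). Its level gives no check of the NS-DADm label, since the mutations alter the protein and not necessarily the amount of RNA. In KO hearts Hdac1 rose from 14.7 ± 1.24 to 18.2 ± 1.55 FPKM and Hdac2 fell from 38.3 ± 0.867 to 29.7 ± 1.13 (limma adjusted p = 0.00591 and 3.65e-05). Ncor1 was at 21.4 ± 0.3 in WT and 22.8 ± 0.662 in KO hearts, which did not pass (0.0982). In NS-DADm hearts Hdac1 was at 13.1 ± 0.975 and 14.4 ± 0.644 FPKM and Hdac2 at 35.5 ± 0.897 and 29.0 ± 1.98, neither past the threshold (limma adjusted p = 0.386 and 0.0579).

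**Figure D1:**
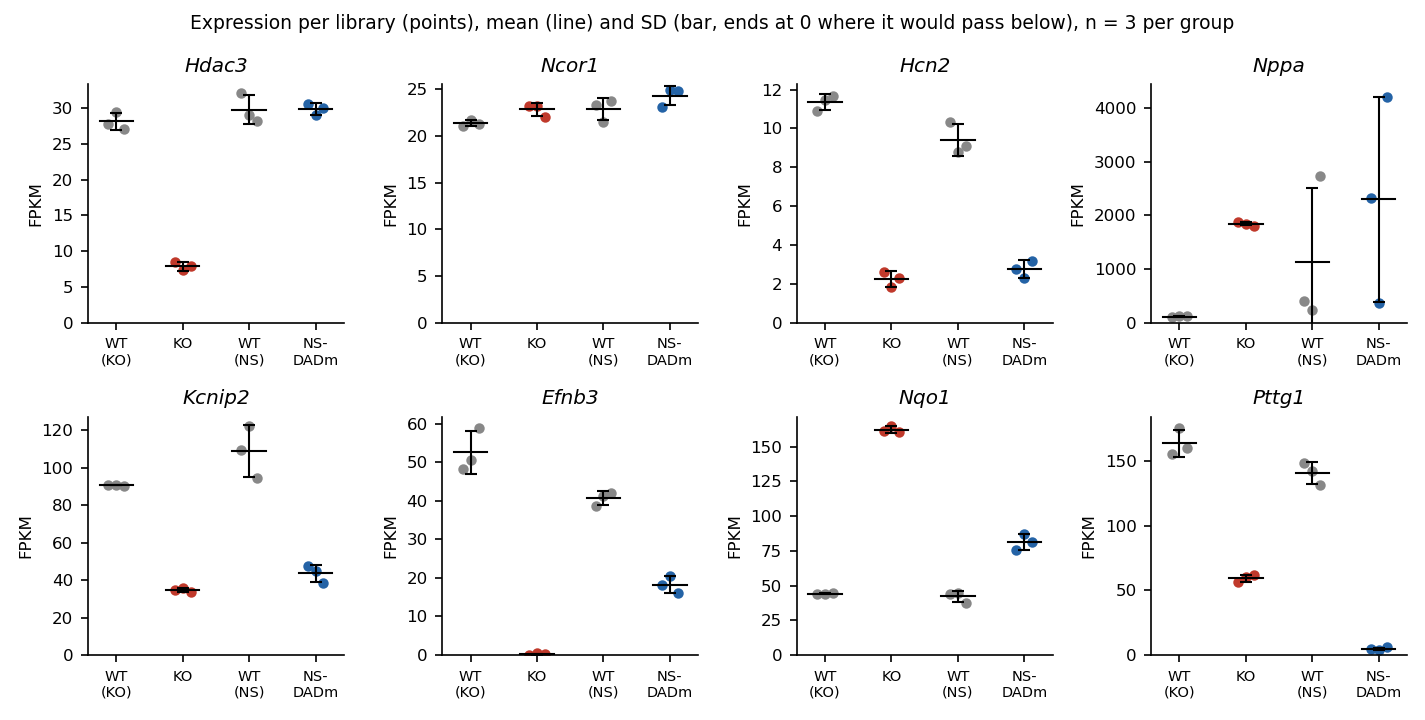
FPKM of 8 genes in each of the 12 libraries (points), with the group mean (long line) and the SD (bar, n = 3), for WT and KO hearts and for the other WT and NS-DADm hearts, on linear axes from 0. Hdac3 falls from 28.1 to 7.9 FPKM in KO hearts and is at 29.8 FPKM in both groups of the NS-DADm experiment, while Efnb3, Hcn2, Kcnip2 and Pttg1 are lower and Nqo1 is higher in both mutants.

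In KO hearts genes of the extracellular matrix, of the fetal heart program and of macrophages rose, and genes of respiration, fatty acid oxidation and branched chain amino acid breakdown fell. None of these lists was called by camera with an estimated correlation, where their adjusted p was 0.0578 to 0.0725. The matrix genes Thbs4 and Cilp rose from 1.77 ± 0.327 to 120.9 ± 2.42 FPKM (68.3-fold) and from 1.57 ± 0.261 to 106.4 ± 1.34 FPKM (67.8-fold; SD, n = 3). Nppa, which encodes atrial natriuretic peptide, rose 15.9-fold from 116.4 ± 3.9 to 1845.5 ± 32.0 FPKM. Efnb3, a membrane-bound ephrin ligand, fell 210.0-fold from 52.6 ± 5.59 to 0.25 ± 0.137 FPKM. Limma gave adjusted p = 3.2e-12, 2.1e-12, 1.59e-13 and 1.51e-11 for these 4 genes.

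Among the other leading rises were Lgals3, which encodes galectin-3 (3.58 ± 0.739 to 172.7 ± 7.53 FPKM, 48.3-fold), Spp1, which encodes osteopontin (0.523 ± 0.095 to 24.9 ± 1.54, 47.6-fold), and Nmrk2, a nicotinamide riboside kinase (4.9 ± 0.229 to 121.0 ± 3.02, 24.7-fold). Mthfd2, an enzyme of mitochondrial folate metabolism, rose 21.1-fold from 2.51 ± 0.4 FPKM, and Serpinb1a, a protease inhibitor, rose 21.0-fold from 3.25 ± 0.83 to 68.3 ± 3.29. The leading falls included Scd4, a fatty acid desaturase (16.2 ± 1.02 to 0.143 ± 0.0379 FPKM, 113.0-fold), the kinase Mylk4 (47.9 ± 0.497 to 0.907 ± 0.18, 52.9-fold) and the myosin heavy chain Myh7b (14.6 ± 0.949 to 0.403 ± 0.0681, 36.2-fold). They also included the receptor Gpr22 (14.3 ± 0.599 to 0.53 ± 0.0529, 27.0-fold), Ptgds, which makes prostaglandin D2 (628.2 ± 20.7 to 27.6 ± 1.79, 22.8-fold), and Scgb1c1 (32.9 ± 2.12 to 1.7 ± 0.943, 19.3-fold). The phospholipase Pla2g5 fell 17.3-fold (26.2 ± 1.75 to 1.51 ± 0.11) and the homeodomain gene Hopx 11.9-fold (204.7 ± 10.7 to 17.3 ± 1.52). Limma adjusted p was between 5.03e-13 and 5.09e-06 for these 13 genes. Ddx3y and Eif2s3y, both on the Y chromosome, also stood among the 10 largest rises.

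The called lists of energy metabolism moved down over most of their measured genes. All 36 measured genes of oxidative phosphorylation fell (median log2 fold change -0.69, camera adjusted p = 1.02e-18). Among them were the complex II subunit Sdhb, from 1199.5 ± 25.1 to 586.4 ± 11.5 FPKM, and the complex I subunit Ndufs1, from 358.3 ± 8.35 to 185.5 ± 0.558 (SD, n = 3). Of 29 genes of fatty acid uptake and oxidation 26 fell and 2 rose (1.9e-12). Ech1 fell from 2235.4 ± 53.7 to 835.8 ± 5.89 FPKM, the thiolase Acaa2 from 952.1 ± 25.9 to 304.3 ± 7.9 and the thioesterase Acot1 from 35.0 ± 1.16 to 3.77 ± 0.323. Those that rose were Acsl6, from 4.41 ± 0.33 to 8.83 ± 0.365, and Fabp3, from 8520.1 ± 106.5 to 9212.3 ± 74.7, whose call was lost when the libraries were centred on their medians. Branched chain amino acid catabolism had 21 of 22 genes lower (1.37e-10), such as Acat1 (283.6 ± 3.89 to 119.8 ± 1.29) and Mccc2 (38.4 ± 1.47 to 14.4 ± 0.461). PPAR target genes had 16 of 20 lower and 1 higher, Fabp3 (3.91e-08). The TCA cycle had 17 of 20 genes lower, such as Idh3b (841.0 ± 33.2 to 440.7 ± 2.99), and 3 higher (7.82e-07). They included the pyruvate carrier Mpc1 (905.8 ± 44.7 to 1224.9 ± 10.9) and Cs, whose call was lost with median centring. These 5 lists had an adjusted p = 0.0578 with an estimated correlation. Counts in this paragraph, apart from those of the cardiomyocyte markers, were equal when adjusted over the list alone. In ketone body metabolism 5 of 7 genes fell and Slc16a1 rose, from 67.6 ± 3.69 to 87.2 ± 1.63 (camera adjusted p = 0.0139, and adjusted p = 0.309 with an estimated correlation). In lipid droplet and triglyceride metabolism 13 of 23 fell and 4 rose (0.00423, and adjusted p = 0.154 with an estimated correlation). Dgat2, which makes triglycerides, fell from 186.2 ± 5.03 to 74.6 ± 1.8. Of the cardiomyocyte markers 9 of 16 fell and 5 rose (median log2 fold change -0.44), while 19 of 20 macrophage and 10 of 10 myofibroblast markers rose. Any marker under 1 FPKM in every WT library could only rise. Levels in whole tissue do not separate a change within cardiomyocytes from a change in their share.

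Of the nuclear receptors and coactivators, 16 of 28 fell and 6 rose, with 3 rising without KO replicate 1 or 3 (17 and 7 adjusted over the list alone; camera adjusted p = 0.0168, and adjusted p = 0.226 with an estimated correlation). Ppara, a receptor that drives fatty acid oxidation genes, fell from 14.3 ± 0.605 to 6.66 ± 0.205 FPKM, Ppargc1a, a coactivator of mitochondrial genes, from 23.9 ± 0.28 to 11.5 ± 0.701 and the retinoid receptor Rxrg from 63.8 ± 3.16 to 29.9 ± 0.696 (SD, n = 3; limma adjusted p = 8.81e-08, 5.5e-08 and 7.89e-09).

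Matrix and fetal genes rose together. All 35 measured genes of extracellular matrix and fibrosis rose (median log2 fold change 1.63, camera adjusted p = 5.83e-18). Members under 1 FPKM in every WT library, such as Spp1, were tested only through the KO libraries and could only rise. Counts and list tests in this paragraph can lean upward for that reason. Col1a1 went from 19.7 ± 0.128 to 103.0 ± 2.71 FPKM, Postn from 13.6 ± 0.698 to 176.6 ± 1.49 and the metalloproteinase inhibitor Timp1 from 4.05 ± 0.291 to 65.8 ± 2.34 (SD, n = 3). All 10 myofibroblast markers rose (8.97e-07), such as smooth muscle actin, Acta2, from 82.1 ± 2.94 to 233.9 ± 1.34. In the fetal gene program and wall stress list 17 of 18 rose and none fell (median 2.23, 9.75e-11). They included skeletal actin, Acta1 (211.4 ± 7.12 to 2050.6 ± 22.1), Ankrd1 (638.1 ± 14.7 to 3939.9 ± 14.8) and Ctgf (24.9 ± 0.4 to 358.5 ± 0.953). These 3 lists had an adjusted p = 0.0578 with an estimated correlation. Fibroblast markers were mixed, 10 of 15 rising and 3 falling (camera adjusted p = 0.0201, and adjusted p = 0.146 with an estimated correlation). Those that fell were Gsn, Fbln1 (50.6 ± 2.33 to 21.7 ± 0.658) and Tcf21 (10.7 ± 1.99 to 6.15 ± 0.755). Counts were equal adjusted over the list alone.

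Lists of macrophage, MHC class II, inflammation and interferon genes were called as higher. Any member under 1 FPKM in every WT library was tested only through the KO libraries and could only rise. Their counts and list tests can therefore lean upward. Of 20 macrophage and monocyte markers 19 rose and none fell (median log2 fold change 2.18, camera adjusted p = 1.16e-10, and adjusted p = 0.0725 with an estimated correlation). The complement gene C1qc rose from 38.4 ± 1.32 to 214.6 ± 3.1 FPKM, Lyz2 from 135.0 ± 7.59 to 793.2 ± 11.3 and Ms4a7 from 2.09 ± 0.0757 to 36.7 ± 1.08 (SD, n = 3). All 7 MHC class II genes rose (5.46e-05, and adjusted p = 0.137 with an estimated correlation), such as Cd74, from 165.7 ± 7.3 to 425.3 ± 14.7. Of 31 inflammation and chemokine genes 23 rose and 6 fell (0.000468, and adjusted p = 0.0631 with an estimated correlation). The chemokine Ccl8 rose from 3.7 ± 0.448 to 70.5 ± 5.34, and the falls were those of Nfkbia, Lcn2, Cxcl12, Vcam1, C3 and S100a9. The interferon list had 24 of 33 higher, Irf7 among them (12.5 ± 0.359 to 36.2 ± 1.39), and 5 lower (0.00286, and adjusted p = 0.168 with an estimated correlation). The latter included Iigp1, Irgm1, Gbp7 and Gbp6, the last from 34.5 ± 2.25 to 10.7 ± 0.446. Counts were equal adjusted over the list alone.

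Genes of rhythm, calcium and adrenergic signalling were mostly lower. Of 24 ion channel and conduction genes 20 fell and 3 rose (4 adjusted over the list alone; camera adjusted p = 1.74e-07, and adjusted p = 0.0578 with an estimated correlation). The subunit of the ATP-sensitive potassium channel Abcc9 fell from 60.2 ± 2.77 to 11.8 ± 0.175 FPKM, Kcnj3 from 26.1 ± 0.726 to 5.63 ± 0.122 and Kcnip2, a subunit of the channel of the transient outward current, from 90.8 ± 0.235 to 34.8 ± 1.26 (SD, n = 3). Those that rose included Kcnd2 and the gap junction gene Gja1 (131.8 ± 4.29 to 158.1 ± 1.98). Of 22 calcium handling genes 15 fell and 6 rose (0.00286, and adjusted p = 0.0989 with an estimated correlation). Hrc, a calcium-binding protein of the sarcoplasmic reticulum, fell from 482.2 ± 11.8 to 70.4 ± 2.35, the calcium pump Atp2a2 from 3685.0 ± 94.8 to 2108.0 ± 26.5 and its regulator Pln from 4006.1 ± 134.1 to 1953.1 ± 20.7. Among those that rose were Sln (2.83 ± 1.09 to 35.5 ± 2.54), Slc8a1, Camk2d and Fkbp1b. In the natriuretic, adrenergic and renin-angiotensin list 11 of 18 fell and 2 rose (0.00324, and adjusted p = 0.233 with an estimated correlation). The adrenergic receptors Adra1a and Adra1b fell from 6.99 ± 0.29 to 0.46 ± 0.141 and from 14.8 ± 0.646 to 1.3 ± 0.231.

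Of 16 cardiomyocyte markers 9 fell and 5 rose (10 and 5 adjusted over the list alone; camera adjusted p = 0.0138, and adjusted p = 0.146 with an estimated correlation). Myl2, the ventricular myosin light chain, fell from 22844.2 ± 855.2 to 9660.2 ± 141.9 FPKM and Tnni3 from 8192.7 ± 478.3 to 3060.6 ± 41.5. Mybpc3 rose from 815.6 ± 15.5 to 1742.2 ± 24.3, Nkx2-5 from 42.6 ± 1.04 to 61.4 ± 2.87 and Gata4 from 38.4 ± 2.29 to 49.7 ± 2.69 (SD, n = 3). Among endothelial markers 11 of 14 fell and 2 rose, with the water channel Aqp1 going from 140.5 ± 4.33 to 61.8 ± 2.02 (0.00422, and adjusted p = 0.146 with an estimated correlation). All 6 erythroid markers fell, such as the globin Hbb-bs from 3389.9 ± 208.0 to 1092.1 ± 15.4 (2.43e-05, and adjusted p = 0.11 with an estimated correlation). Of 12 immediate early and dissection stress genes 11 rose and none fell, such as Ier3 from 32.0 ± 1.67 to 128.2 ± 0.38 (4.02e-05, and adjusted p = 0.11 with an estimated correlation). Apart from the cardiomyocyte list the counts were equal adjusted over the list alone.

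The antioxidant, unfolded protein and cell cycle lists were called as higher and the hypoxia list as lower, with counts that were equal adjusted over the list alone except where given. Of 26 antioxidant genes 19 rose and 4 fell (camera adjusted p = 0.000468, and adjusted p = 0.101 with an estimated correlation). The quinone reductase Nqo1 went from 44.2 ± 0.201 to 162.3 ± 2.46 FPKM, Hmox1 from 7.55 ± 0.748 to 48.8 ± 1.7 and the metallothionein Mt2 from 55.8 ± 4.25 to 494.1 ± 28.4 (SD, n = 3). Sod1, Gpx3, Gsta3 and Sod2 fell, the last from 232.8 ± 2.81 to 135.9 ± 1.93. Of 34 genes of the unfolded protein and integrated stress response 23 rose and 3 fell (0.00051, and adjusted p = 0.11 with an estimated correlation). The falls were those of Herpud1, Vldlr and Atf6, the last losing its call without KO replicate 1 or 2 (limma adjusted p = 0.0787 and 0.066). Atf5 went from 28.7 ± 1.27 to 130.9 ± 5.27 and the amino acid synthesis genes Asns from 1.76 ± 0.341 to 22.1 ± 1.73 and Psat1 from 1.96 ± 0.193 to 12.9 ± 0.439. Of 32 cell cycle genes 26 rose, such as Mki67, from 0.757 ± 0.159 to 4.2 ± 0.255, and Top2a, from 0.737 ± 0.0289 to 3.73 ± 0.0624. Mki67 and Top2a were under 1 FPKM in WT and so were tested only through the KO libraries, which fixes their direction. The 3 cell cycle genes that fell were Cenpf, Ccnd3 and Ccnd2 (29.6 ± 0.577 to 12.9 ± 0.306). The call of this list (0.00134, and adjusted p = 0.11 with an estimated correlation) was lost without KO replicate 1, 2 or 3 (adjusted p = 0.247, 0.315 and 0.345), where 17 of its genes were still tested and 10 rose. In the hypoxia list 9 of 19 fell and 4 rose (11 and 4 adjusted over the list alone). Ddit4 fell from 21.9 ± 0.534 to 7.01 ± 0.744 and the glucose transporter Slc2a1 rose from 6.79 ± 0.287 to 19.0 ± 1.12. Its call (0.0335, and adjusted p = 0.154 with an estimated correlation) was lost without KO replicate 1 (0.0641).

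Of the 52 lists tested, 24 were not called by camera, and most had members on both sides. Apoptosis had 19 of 32 genes higher and 5 lower (camera adjusted p = 0.13), muscle atrophy 7 of 19 higher and 10 lower (0.13), and the sarcomere 8 of 23 higher and 11 lower (0.157; 12 lower adjusted over the list alone). Heat shock had 12 of 22 higher and 7 lower (0.409; 8 lower adjusted over the list alone), and p53 targets 11 of 22 higher and 6 lower (0.418). Glycolysis had 11 of 24 higher, with Gapdh going from 4537.9 ± 72.9 to 10898.9 ± 319.8 FPKM (SD, n = 3), and 10 lower (0.996). Skeletal muscle isoforms had 3 of 8 higher and 4 lower (0.954; 5 lower adjusted over the list alone), and the light chain Myl1 rose from 67.5 ± 3.61 to 904.1 ± 4.59. This list's median log2 fold change of -0.26 had the opposite sign to its mean of 0.76 and to its test. In 5 lists the majority turned with median centring. Autophagy went from 11 higher and 8 lower to 7 and 12, cholesterol synthesis from 7 and 6 to 4 and 8, and fatty acid synthesis from 7 and 6 to 6 and 8. Cell cycle inhibitors went from 7 and 6 to 7 and 8, and the HDAC3 corepressor list from 7 and 6 to 5 and 6. Single members of uncalled lists still moved far, such as Cdkn1a, the inhibitor p21 (18.9 ± 1.28 to 92.3 ± 1.06), Des (752.7 ± 11.4 to 2952.4 ± 40.4), the autophagy receptor Sqstm1 (231.3 ± 4.72 to 904.9 ± 5.83) and Fkbp4 (199.2 ± 4.23 to 51.3 ± 0.947). Atrial cardiomyocyte markers had 5 of 8 higher and 3 lower (0.41), among them Myl4 (9.01 ± 1.01 to 79.2 ± 3.17). T cell, B cell, neutrophil, Schwann, valve, lymphatic, adipocyte, smooth muscle and skeletal fibre markers were not called either (adjusted p between 0.409 and 0.732). Without WT replicate 1, 2 or 3 the skeletal muscle isoforms had 2, 2 and 3 lower, and without KO replicate 1, 2 or 3 they had 2 higher. Cholesterol synthesis had 6 higher and 4 lower without WT replicate 3. Without KO replicate 1, 2 or 3 it had 5, 4 and 6 higher and 4, 4 and 7 lower.

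Limma called 7775 of 11810 tested genes in KO hearts (65.8%), 4515 higher and 3260 lower, or 58.1% higher. Of these, 1198 changed by at least 2-fold (814 higher, 384 lower). Median centring, which shifts the log2 fold changes by -0.09, gave 7790 calls of which 46.7% were higher. In 8248 of the 11810 genes (69.8%) every KO library lay on one side of every WT library, where chance gives 10%. The KO and WT libraries also differ in sex-linked genes. Ddx3y and Kdm5d were listed at 0 in the WT and were at 21.7 ± 0.391 and 3.01 ± 0.139 FPKM in the KO libraries. Eif2s3y was at 0.11 and 47.0 ± 1.35 and Uty at 0.01 ± 0.0173 and 6.55 ± 0.225. These 4 Y-linked genes were the tested members of the sex chromosome list (camera adjusted p = 0.000546, and adjusted p = 0.137 with an estimated correlation). They were tested only through the KO libraries, which fixes their direction. The X-linked partners Kdm6a, Kdm5c, Eif2s3x and Ddx3x, not in that list, were lower in KO libraries. A difference of sex between the KO and WT libraries can therefore not be separated from that of genotype. No list kept its call with an estimated correlation, where the smallest adjusted p was 0.0578, against 28 calls with the preset one and 47 with fry, which tests each list without comparing it with other genes. Splits of these libraries that mix the genotypes called 13 to 21 lists with the preset correlation. A list call alone is therefore weak evidence of a genotype effect.

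In NS-DADm hearts far fewer genes passed the threshold, and leading changes included falls of Pttg1, Cyfip2 and Ndrg4 and rises of Myot and Nnt. Pttg1, which encodes securin, fell 30.1-fold from 140.3 ± 8.56 to 4.67 ± 1.1 FPKM, Cyfip2, an actin regulator, 16.6-fold from 43.5 ± 3.3 to 2.62 ± 0.302, and Ndrg4 4.42-fold from 107.1 ± 6.48 to 24.2 ± 4.71 (SD, n = 3; limma adjusted p = 8.9e-07, 8.85e-08 and 0.000313). Myot, which encodes the Z-disc protein myotilin, rose 3.16-fold from 29.3 ± 3.32 to 92.7 ± 12.5 FPKM, and Nnt, the mitochondrial transhydrogenase that makes NADPH, 2.35-fold from 194.2 ± 6.02 to 456.6 ± 30.8 (0.000313 and 3.15e-05). Limma called 315 of 11705 tested genes (2.7%), 148 higher and 167 lower.

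Other leading rises in NS-DADm hearts were the metalloproteinase Mmp9 (0.37 ± 0.226 to 3.23 ± 0.172 FPKM), Wdfy1 (2.67 ± 0.25 to 9.67 ± 1.42), Cdkn1a (13.9 ± 2.8 to 34.0 ± 3.57), the complement factor Cfp (5.23 ± 0.558 to 12.8 ± 1.34) and Olfr1372-ps1, an olfactory receptor pseudogene (0.897 ± 0.229 to 7.84 ± 0.793; SD, n = 3; limma adjusted p between 3.15e-05 and 0.00538). Fcna, Lrrc52 and the immediate early gene Nr4a1 also stood among the 10 largest rises (limma adjusted p = 0.00827, 0.0388 and 0.0326). Fcna lost its call without WT replicate 2 (0.0542), Lrrc52 without WT replicate 1 or 2 or NS-DADm replicate 1 (0.0828, 0.136 and 0.0978). Nr4a1 lost it without WT replicate 1, 2 or 3 or NS-DADm replicate 1 or 2 (0.11, 0.145, 0.0808, 0.0662 and 0.086). Leading falls were the channel genes Hcn2 (9.41 ± 0.826 to 2.76 ± 0.461), Kcnip2 (108.9 ± 14.0 to 43.7 ± 4.52) and Kcne1 (2.3 ± 0.23 to 0.447 ± 0.243). Efnb3 (40.7 ± 1.89 to 18.3 ± 2.2) and Lrrc15 (6.64 ± 0.862 to 2.72 ± 0.0252) fell too (limma adjusted p between 0.000313 and 0.00368 for these 5 genes). Olfr1396 was at 1.27 ± 0.178 in WT and had no listed value, taken as 0, in the NS-DADm libraries (0.00185). Both olfactory genes belong to a family of near-identical copies, among which reads can be split.

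Macrophage and monocyte markers were the leading list in NS-DADm hearts, with 7 of 18 higher and none lower (14 higher adjusted over the list alone; median log2 fold change 0.37, camera adjusted p = 3.69e-13, and adjusted p = 0.187 with an estimated correlation). C1qa rose from 60.3 ± 2.31 to 83.7 ± 3.94 FPKM and C1qc from 45.0 ± 1.52 to 67.0 ± 6.39 (SD, n = 3; limma adjusted p = 0.00629 and 0.00709). The MHC class II list had 1 of 7 higher (5 adjusted over the list alone), the lysosomal protease Ctss, from 13.2 ± 0.39 to 30.0 ± 3.34 (camera 1.9e-06, and adjusted p = 0.434 with an estimated correlation). Inflammation had 4 of 23 higher both ways (1.94e-06, and adjusted p = 0.341 with an estimated correlation). They included the chemokines Ccl6 (14.9 ± 2.42 to 31.7 ± 3.08) and Ccl9 (4.35 ± 0.47 to 7.81 ± 0.469). Antioxidant genes had 4 of 26 higher (9 adjusted over the list alone), such as Nqo1, from 42.3 ± 4.14 to 81.5 ± 5.91 (4.09e-06, and adjusted p = 0.321 with an estimated correlation). The unfolded protein and integrated stress response had 5 of 33 higher (8 adjusted over the list alone; 5.28e-07, and adjusted p = 0.154 with an estimated correlation). Immediate early genes had 3 of 11 higher (6 adjusted over the list alone; 1.96e-07, and adjusted p = 0.341 with an estimated correlation), and nuclear receptors 3 of 28 (4 adjusted over the list alone; 0.00271, and adjusted p = 0.327 with an estimated correlation). By fry the MHC class II, inflammation and immediate early lists were not called (adjusted p = 0.116, 0.118 and 0.116). All 7 lists kept their camera call without any single library, but the numbers of genes did not hold. Without WT replicates 1 to 3 or NS-DADm replicates 1 to 3, 3, 2, 5, 3, 5 and 6 macrophage markers and 1, 1, 1, 1, 2 and 1 MHC class II genes were higher. In the same order, 2, 2, 3, 2, 5 and 3 inflammation genes and 1, 2, 3, 3, 3 and 2 antioxidant genes were higher. For the unfolded protein and integrated stress response the numbers were 0, 1, 3, 0, 4 and 6, for immediate early genes 1, 0, 1, 0, 1 and 2, and for nuclear receptors 0, 0, 1, 0, 0 and 3.

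Ion channel and conduction genes had 4 of 25 lower and 1 higher (9 and 1 adjusted over the list alone; camera adjusted p = 0.000961, and adjusted p = 0.341 with an estimated correlation), with Hcn2, Kcnip2 and Kcne1 among the falls. The interferon response was called as higher (32 genes, median log2 fold change 0.21, camera adjusted p = 7.45e-07, and adjusted p = 0.568 with an estimated correlation), as was extracellular matrix and fibrosis (33 genes, median 0.16, 0.000479, and adjusted p = 0.604 with an estimated correlation). In both lists 0 members passed by limma, also when adjusted over the list alone, while 8 higher interferon genes, and 7 higher and 2 lower matrix genes, had an unadjusted p under 0.05 and the authors' deposited table called 1 and 3 as higher. Erythroid markers were called as lower with 0 members passing by limma, 0 at an unadjusted p under 0.05 and 0 in the authors' deposited table (6 genes, median -0.59, 0.00376, and adjusted p = 0.604 with an estimated correlation). Fatty acid synthesis was called as higher with 0 members passing by limma, 3 of 18 at an unadjusted p under 0.05, all higher, and 0 in the authors' deposited table (0.00139, and adjusted p = 0.604 with an estimated correlation; 0.0765 without NS-DADm replicate 3). Without WT replicates 1 to 3 or NS-DADm replicates 1 to 3, 2, 2, 3, 3, 4 and 5 ion channel genes were lower and 0, 0, 0, 0, 0 and 1 higher. The matrix list had 1 gene higher without WT replicate 3, the interferon list 1 higher without NS-DADm replicate 2, and the erythroid list 2 lower without NS-DADm replicate 1.

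The remaining 5 calls among the lists of NS-DADm hearts were each lost when a single library was left out, and their counts were equal adjusted over the list alone except where given. Fatty acid uptake and oxidation was lower, with 1 of its 29 members falling (camera adjusted p = 0.0141, and adjusted p = 0.636 with an estimated correlation), and lost its call without WT replicate 1 or 2 or NS-DADm replicate 1 or 3 (0.0618, 0.0552, 0.166 and 0.0888). Branched chain amino acid catabolism was lower (0.0186, and adjusted p = 0.604 with an estimated correlation). Of its 22 members 0 passed by limma, 1 when adjusted over the list alone, 5 at an unadjusted p under 0.05, all lower, and 0 in the authors' deposited table. It lost its call without WT replicate 2 or NS-DADm replicate 1 (0.106 and 0.166). Lipid droplet genes had 1 of 26 higher (0.0175, and adjusted p = 0.574 with an estimated correlation; 0.214 without NS-DADm replicate 3). Adipocyte markers had 1 of 9 higher (0.0212, and adjusted p = 0.636 with an estimated correlation; 0.0618, 0.127 and 0.521 without WT replicate 1, WT replicate 2 or NS-DADm replicate 3). The hypoxia list had 1 of 19 higher, Bnip3, from 128.7 ± 8.96 to 190.8 ± 11.3 FPKM (SD, n = 3; camera 0.0398, and adjusted p = 0.341 with an estimated correlation; 0.154, 0.0584 and 0.0568 without WT replicate 1, WT replicate 2 or NS-DADm replicate 2). Lipid droplet genes had 1 higher without WT replicate 3, 0 higher without any other library and 1 lower without NS-DADm replicate 3, and adipocyte markers 0 without any one of the 6.

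Lists called in KO hearts and not called in NS-DADm hearts included oxidative phosphorylation (36 genes, median log2 fold change -0.05, camera adjusted p = 0.121), the TCA cycle (20 genes, -0.06, 0.063) and cell cycle (20 genes, -0.02, 0.935), whose KO call was lost without KO replicate 1, 2 or 3 (0.247, 0.315 and 0.345). The cell cycle list had 32 tested genes in KO hearts, some of them tested only through the KO libraries. In NS-DADm hearts 0 members of the 3 lists passed by limma, and adjusted over the list alone 0, 3 and 2 did, all lower. At an unadjusted p under 0.05 the 3 lists had 5, 5 and 2 members lower and 0, 1 and 1 higher, and the authors' deposited table called 0, 0 and 1, the last as lower. PPAR targets had 1 of 22 lower both ways (median -0.11, 0.0687). In calcium handling (0.1) 3 of 21 genes fell, among them Hrc, from 525.9 ± 39.1 to 367.1 ± 13.5 FPKM (SD, n = 3; limma adjusted p = 0.0063). Fry, unlike camera, did call this list (adjusted p = 0.0118). This list had a median of -0.06 and a mean of 0.03, with 6 lower and 1 higher adjusted over the list alone. The sarcomere list (0.345) had Myot higher and 3 of 23 genes lower (3 higher and 4 lower adjusted over the list alone), among them tropomyosin, Tpm1, from 9423.4 ± 167.3 to 6622.1 ± 423.3 (0.00573). In the p53 list (0.986; median -0.03, mean 0.05) 2 of 21 rose and 2 fell (3 adjusted over the list alone), the falls being Ccng1, from 402.0 ± 22.6 to 232.1 ± 13.9, and Perp, from 113.8 ± 3.86 to 86.4 ± 1.93 (0.000606 and 0.00866). In the list of HDAC3 corepressor genes (0.282; 1 of 16 higher and 1 lower, or 1 and 3 adjusted over the list alone) Tbl1xr1, a subunit of these complexes, rose from 6.8 ± 0.267 to 12.2 ± 0.762 (0.00146). Without WT replicates 1 to 3 or NS-DADm replicates 1 to 3, calcium handling had 1, 1, 1, 1, 2 and 1 genes lower, and the sarcomere 1, 1, 3, 2, 1 and 1 lower and 1, 1, 1, 2, 1 and 1 higher. In the same order, the p53 list had 1, 2, 2, 1, 2 and 2 higher and the HDAC3 corepressor list 0, 0, 0, 0, 0 and 1 lower. Oxidative phosphorylation had 1 lower without WT replicate 3, and PPAR targets 2 lower without NS-DADm replicate 3.

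**Figure D2:**
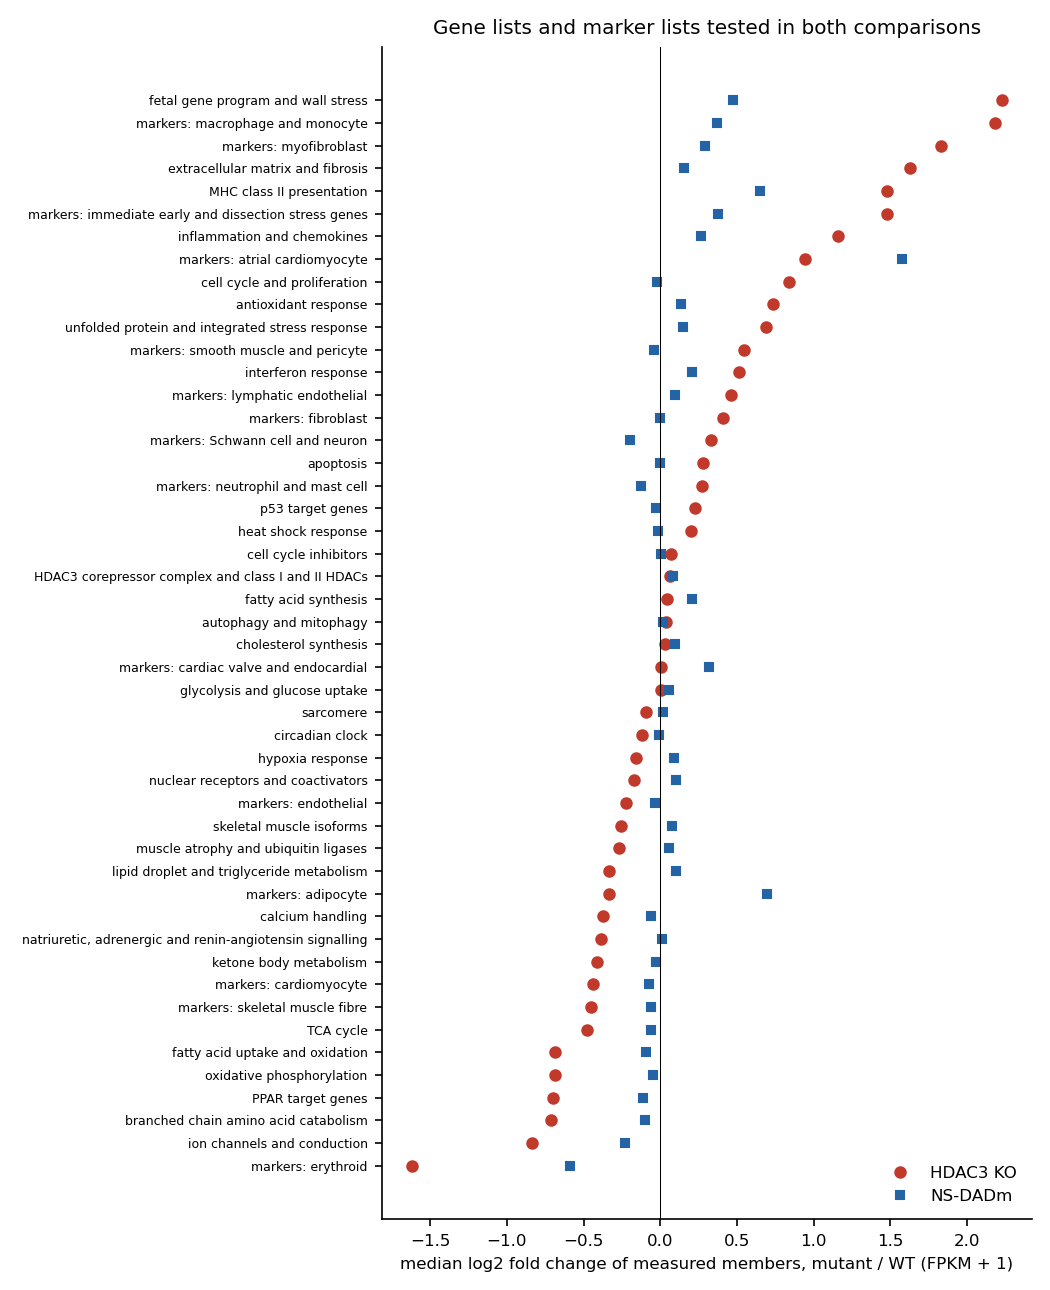
Median log2 fold change (FPKM + 1) over the tested members of each gene list fixed before the data were examined, for KO against its WT (red circles) and NS-DADm against its WT (blue squares), with a line at 0. Oxidative phosphorylation lies at -0.69 in KO and -0.05 in NS-DADm hearts, and extracellular matrix and fibrosis at 1.63 and 0.16.

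**Figure D3:**
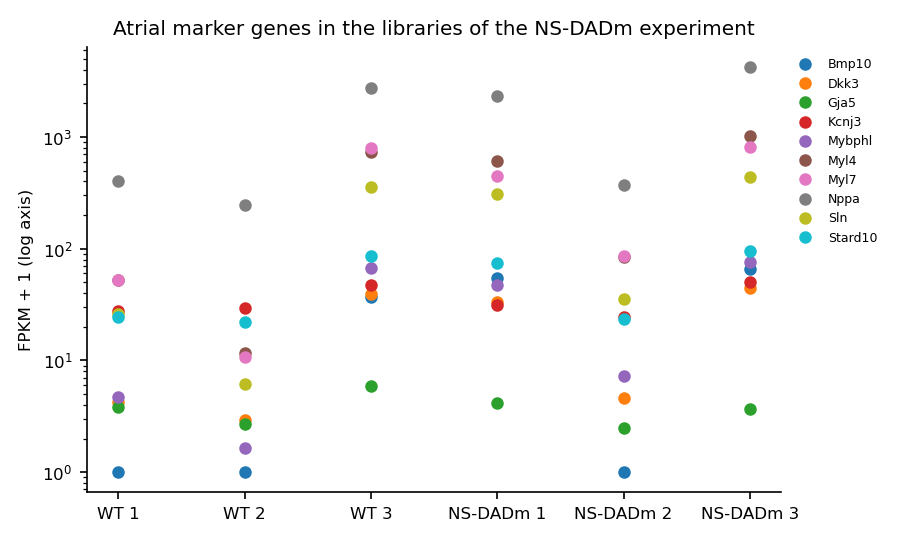
FPKM + 1 of 10 atrial cardiomyocyte markers on a log axis in the 3 WT and the 3 NS-DADm libraries of that experiment, one point per library. WT replicate 3 and NS-DADm replicates 1 and 3 lie above the other libraries for 9 of the 10 markers.

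Libraries of the NS-DADm experiment differed in atrial genes in a way that does not follow the genotype. Nppa was at 403.98, 243.31 and 2728.12 FPKM in WT replicates 1 to 3 and at 2329.25, 369.76 and 4203.68 FPKM in NS-DADm replicates 1 to 3. Bmp10 had no listed value, taken as 0, in WT replicates 1 and 2 and NS-DADm replicate 2 and lay between 35.76 and 64.77 FPKM in the other libraries. Of 10 atrial markers measured, 9 were higher in WT replicate 3 and NS-DADm replicates 1 and 3 than in every other library, the exception being Gja5. The list had a median log2 fold change of 1.58 and was not called (camera adjusted p = 0.063). The fetal gene program list shares Nppa, Myl4, Myl7 and Mybphl with it and was called as higher (median 0.47, 1.04e-05, and adjusted p = 0.341 with an estimated correlation). It had 3 of 20 members higher (6 higher and 1 lower adjusted over the list alone), among them Flnc, from 37.1 ± 1.46 to 55.9 ± 2.25 FPKM (SD, n = 3; limma adjusted p = 0.00205). With the mean of the atrial markers as a covariate in all 6 libraries, 267 genes and 15 lists were called. Of the 18 lists 4 then lost their call, namely branched chain amino acid catabolism, fatty acid uptake and oxidation, hypoxia and adipocyte markers (camera adjusted p = 0.186, 0.319, 0.0601 and 0.431). The 3 libraries of low atrial markers alone are WT replicates 1 and 2 and NS-DADm replicate 2, and the lone NS-DADm library is assumed to vary like the WT libraries. That fit called 182 genes and 12 lists. Of the 18 lists 7 lost their call, the matrix and interferon lists (0.564 and 0.443) among them, which kept it with the covariate. The fetal list had 1, 2, 3, 1, 4 and 2 members higher without WT replicates 1 to 3 or NS-DADm replicates 1 to 3.

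In 2829 of the 11705 genes tested in the NS-DADm experiment (24.2%) the groups were fully separate, where chance gives 10%, and 2153 had an unadjusted p under 0.05. Median centring gave 354 calls, 54.0% of them higher against 47.0% without it, and 59.6%, 56.0% and 55.6% were higher without WT replicate 1, WT replicate 2 or NS-DADm replicate 2. The count of 315 fell to 99, 84 and 148 without WT replicate 1, WT replicate 2 or NS-DADm replicate 1, and 31 of the calls were of at least 2-fold (18 higher, 13 lower). No list was called with an estimated correlation, where the smallest adjusted p was 0.154, against 18 with the preset one and 6 with fry. Of the 18, 5 were also called by fry and 13 were not. The other list called by fry was calcium handling (adjusted p = 0.0118). Splits of these libraries that mix the genotypes called 3 to 19 lists with the preset correlation, so a list call alone is weak evidence.

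Several of the largest changes in NS-DADm hearts lay on chromosome 11, which carries Ncor1. Pttg1, Cyfip2 and Olfr1372-ps1 start 18.9, 16.1 and 10.2 Mb before Ncor1 and Efnb3 starts 7.2 Mb after it. Of the 999 tested genes of chromosome 11, 44 were called (20 higher, 24 lower), or 4.4% against 2.5% of the other genes (Fisher's exact test, two-sided, adjusted p = 0.007 over the chromosomes). Within 25 Mb of the start of Ncor1, 24 of 467 genes were called (5.1% against 2.6%, odds ratio 2.04). Within 5 Mb 2 of 97 were called (2.1% against 2.7%).

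**Figure D4:**
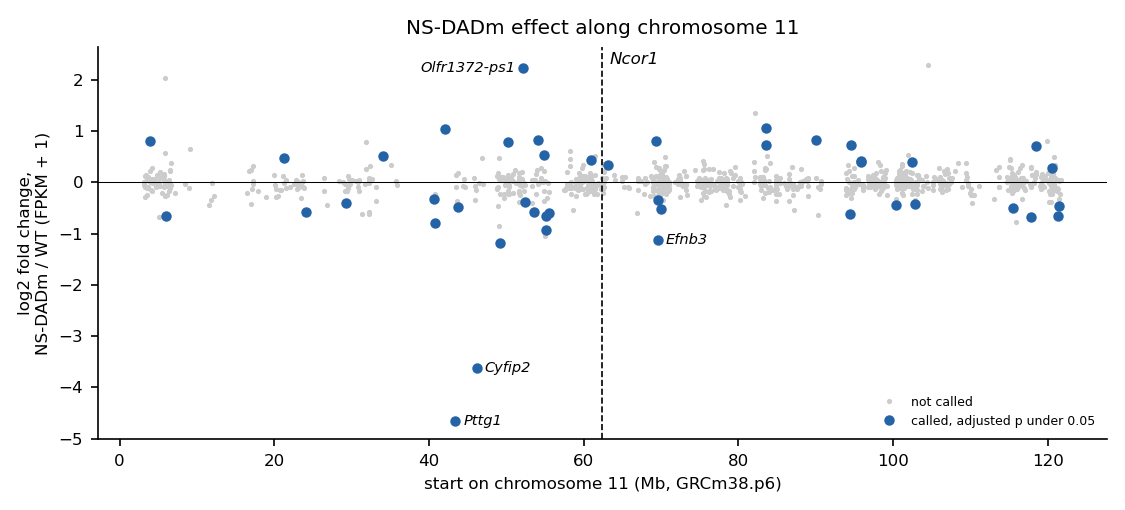
Log2 fold change (FPKM + 1) of NS-DADm against WT for each tested gene of chromosome 11 by its start in Mb (GRCm38.p6), with called genes in blue, others in grey and a dashed line at Ncor1. Pttg1 and Cyfip2 lie lowest, at -4.66 and -3.62, and Olfr1372-ps1 at 2.22 is the highest called gene.

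Most genes called in NS-DADm hearts moved the same way in KO hearts, usually by more. Of 290 NS-DADm calls tested in both experiments, 225 (77.6%) were called in the same direction in KO hearts. Of these, 109 were higher and 116 lower in both, where independent lists would share 50.8 and 43.3 (Fisher's exact test, one-sided, p = 2.63e-24 and 1.19e-34). Hcn2, Kcnip2 and Kcne1 fell in both. Kcnip2 fell 2.61-fold in KO and 2.49-fold in NS-DADm hearts (difference of effects -0.07, limma adjusted p = 0.69), Kcne1 11.3-fold and 5.16-fold (-0.29, 0.162) and Hcn2 5.04-fold and 3.41-fold (-0.46, 0.0212). Cdkn1a, Cfp, Ctss and Ccl6 rose in both, Cfp 2.55-fold and 2.45-fold (0.08, 0.643) and Ctss 6.52-fold and 2.28-fold (1.51, 8.82e-08). Pttg1 went further in NS-DADm than in KO hearts, where it fell 2.75-fold from 163.6 ± 10.6 to 59.5 ± 2.7 FPKM (SD, n = 3; 3.21, 2.27e-09).

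The log2 fold change was larger in size in KO hearts for 180 of these 225 genes, the median ratio of NS-DADm to KO was 0.51, and 152 of the 225 were called in the difference. The overlap of 225 fell to 68, 59 and 108 without the WT replicate 1, the WT replicate 2 or the NS-DADm replicate 1 of the NS-DADm experiment, with 146 without NS-DADm replicate 3. Across the 10889 genes tested in both, which are not independent replicates, the log2 fold changes correlated at r = 0.41 (Spearman's rho 0.35), and 6638 had the same sign.

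**Figure D5:**
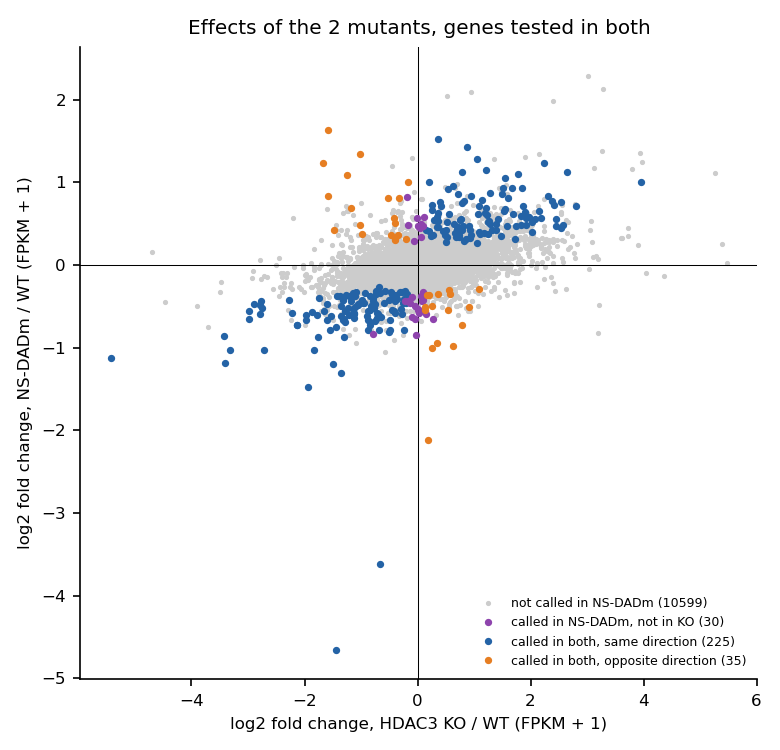
Log2 fold change (FPKM + 1) in KO hearts (horizontal) against NS-DADm hearts (vertical) for the 10889 genes tested in both experiments. The 225 genes called in both in the same direction (blue), the 35 called in opposite directions (orange) and the 30 called in NS-DADm but not KO hearts (purple) stand over all others (grey).

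A test of the difference of the effects asked which KO changes NS-DADm hearts did not show to the same extent. Thbs4, Cilp and Nmrk2 led in the positive direction, with differences of 5.44, 5.14 and 4.50 (log2, KO effect minus NS-DADm effect; limma adjusted p = 4.12e-10, 2.15e-10 and 2.82e-10). In the NS-DADm experiment they were at 1.38 ± 0.0379 and 1.48 ± 0.733, at 1.96 ± 0.276 and 2.57 ± 0.816 and at 3.78 ± 0.546 and 3.41 ± 0.919 FPKM in WT and NS-DADm hearts (SD, n = 3). Mylk4, Efnb3, Ptgds, Scd4 and Myh7b led in the negative direction, with differences of -4.85, -4.30, -4.01, -3.42 and -3.26 (6.9e-12, 8e-11, 2.39e-10, 1.01e-07 and 1.09e-07). Mylk4 was at 79.2 ± 4.16 and 89.2 ± 13.3 FPKM in WT and NS-DADm hearts, and Ptgds at 347.0 ± 44.1 and 254.1 ± 36.3. The Y-linked Eif2s3y and Ddx3y also stood among the 5 largest positive differences (5.46 and 4.53).

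In all, 5348 of 11662 genes were called in the difference (45.9%), 3285 positive and 2063 negative, or 61.4% positive, and 988 by at least 2-fold (676 positive, 312 negative). Median centring shifted the differences by -0.10 and gave 5249 calls, 47.2% of them positive. Of 6852 genes called in KO and not in NS-DADm hearts, 4534 were called in the difference, and for the remainder the test did not show that the effects differ. This test assumes that the effect of each genotype was measured alike in the 2 experiments, which differ in spread and in WT libraries. It also carries any effect of sex, since the KO and WT libraries differ in Y-linked genes while Xist lay between 15.11 and 20.56 FPKM in all 6 libraries of the NS-DADm experiment.

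A smaller set went in opposite directions. Of the 290 NS-DADm calls 35 (12.1%) were called the other way in KO hearts, 16 higher in KO and 19 lower, fewer than the 55.9 and 39.3 that independent lists would share (one-sided Fisher's exact test, p = 1.37e-13 and 3.01e-05). All 35 were also called in the difference, which was nearly fixed by picking genes with called effects of opposite sign. Their calls in the difference are therefore no further evidence. Myot fell in KO hearts from 30.2 ± 2.02 to 9.39 ± 0.988 FPKM, Nnt from 252.7 ± 0.6 to 78.3 ± 0.881 and Agt, which encodes angiotensinogen, from 4.21 ± 0.275 to 1.18 ± 0.0751. All 3 rose in NS-DADm hearts, Agt from 2.85 ± 0.188 to 7.28 ± 1.34 (SD, n = 3). Rbpms2 rose in KO hearts from 18.0 ± 0.49 to 28.4 ± 1.62 and fell in NS-DADm hearts from 31.2 ± 0.392 to 15.4 ± 1.91.

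The authors' deposited table called 5897 genes in KO hearts (2998 higher, 2899 lower) and 433 in NS-DADm hearts (249 higher, 184 lower), at the authors' own limits of q-value and fold change. Of these, 5318 and 245 were also called here, each in the same direction, and 542 and 27 were not tested here. The authors' themed gene sheets were selected from these samples and so are no independent evidence of a direction. In them, 10 of 17 genes of negative regulation of apoptosis were higher and 7 lower in KO hearts by limma, and 6 higher and 3 lower in NS-DADm hearts. Negative regulation of proliferation had 8 of 15 higher and 7 lower in KO hearts, and 7 higher and 3 lower in NS-DADm hearts. The inflammation sheet had 12 of 13 higher and 1 lower in KO hearts, and 5 of 12 higher and 1 lower in NS-DADm hearts. Of the lipid sheet 76 of 184 tested genes were higher and 108 lower in KO hearts, against 5 and 4 of 176 in NS-DADm hearts. The 30 calls over the NS-DADm sheets fell to 11, 10 and 13 without WT replicate 1, WT replicate 2 or NS-DADm replicate 1.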

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

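The test of the difference of effects was planned before the data were examined, and the genes below were picked by the fixed rule for genes called in both comparisons. In 35 genes the KO and NS-DADm effects were called in opposite directions and were also called in the difference. Picking called effects of opposite sign nearly fixes a call in the difference, so it is no independent evidence. The tables were normalized separately, so each value stands only beside the WT of its own experiment. The KO and WT libraries also differ in Y-linked genes, so a difference of effects can include an effect of sex.

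Of genes that fell in KO and rose in NS-DADm hearts, Myot had a difference of effects of -3.21 (log2, KO effect minus NS-DADm effect, limma adjusted p = 1.75e-09), Nnt of -2.91 (2.7e-12) and Agt, also called, of -2.34. Nnt went from 252.7 ± 0.6 to 78.3 ± 0.881 FPKM in KO and from 194.2 ± 6.02 to 456.6 ± 30.8 FPKM in NS-DADm hearts (SD, n = 3), and as background it is known to carry a deletion in the C57BL/6J strain. The strains of these mice are not given in the sources used here. Dct differed by -2.44 (8.14e-08), going from 3.33 ± 0.182 to 0.437 ± 0.0757 in KO and from 1.62 ± 0.434 to 3.69 ± 0.609 in NS-DADm hearts. Its NS-DADm call was lost without WT replicate 2 or NS-DADm replicate 1 (adjusted p = 0.0709 and 0.0665). Lrrc52 differed by -2.35 (2.22e-05), and its NS-DADm call was lost without WT replicate 1 or 2 or NS-DADm replicate 1 (0.0828, 0.136 and 0.0978).

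Of genes that rose in KO and fell in NS-DADm hearts, Rbpms2 had a difference of 1.6 (limma adjusted p = 3.02e-08) and kept its call without any single library. Serf1 differed by 1.5 (0.000422), Nt5c by 1.42 (2.11e-06), Zc4h2 by 1.09 (6.92e-05) and Ap1s2 by 0.72 (1.65e-05), and all 4 lost their NS-DADm call without single libraries. Serf1 lost it without WT replicate 1, 2 or 3 or NS-DADm replicate 1 or 2 (adjusted p = 0.149, 0.133, 0.103, 0.0989 and 0.125). Nt5c lost it without the same libraries (0.127, 0.124, 0.0867, 0.083 and 0.0611), and Zc4h2 without NS-DADm replicate 1, 2 or 3 (0.118, 0.0953 and 0.0697). Ap1s2 lost it without any one of the 6 libraries, WT replicates 1 to 3 (0.0828, 0.145 and 0.0681) or NS-DADm replicates 1 to 3 (0.118, 0.0571 and 0.0828). No explanation was tested for these genes.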

How the results depend on the processing

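Tests chosen only after seeing the data were those with the spread of the NS-DADm experiment, with each experiment's own spread, with the atrial markers as a covariate and with only the 3 libraries of low atrial markers. No called list and no called gene named by the rule reversed under any setting run, but the majority direction of the counts did. With median centring, which shifts the log2 fold changes by -0.09 in KO hearts, 0.01 in NS-DADm hearts and -0.1 for the difference, the share of calls that were higher went from 58.1% to 46.7%, from 47.0% to 54.0% and from 61.4% (positive) to 47.2%. In NS-DADm hearts it also lay over 50%, with the replicate block (52.0%), with a 2-fold minimum (58.1%), in the authors' deposited calls (249 higher, 184 lower) and without WT replicate 1, WT replicate 2 or NS-DADm replicate 2 (59.6%, 56.0% and 55.6%). Among lists not called in KO hearts, median centring turned the majority of 5, such as autophagy from 11 higher and 8 lower to 7 and 12 and cholesterol synthesis from 7 and 6 to 4 and 8. The cause was not tested beyond the shift. The 7775 KO calls stayed within 1.5-fold, between 5854 and 8502, under median centring, no filter, a pseudocount of 0.1, all 12 libraries together (7020), the NS-DADm spread, the authors' deposited calls and each library left out (6814 to 7352). With a 2-fold minimum they were 1198, the calls for the difference 988 against 5348, the NS-DADm calls 31 and the overlap 16 against 225, since this setting adds a condition. The calls for the difference otherwise lay between 4639 and 5641, with 4639 to 5311 when a library was left out.

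The 315 NS-DADm calls changed by more than 1.5-fold under several settings. They were 164 without the filter on low values, 1140 in one fit of all 12 libraries and 182 with only the 3 libraries of low atrial markers, a fit in which the lone NS-DADm library is assumed to vary like the others. Leaving out a library gave 84 to 248, with 99 without WT replicate 1, 84 without WT replicate 2 and 148 without NS-DADm replicate 1. Of the 315, 297 were called in the fit of all 12 libraries and 94 with the 3 libraries alone, where fewer samples were used. Median centring gave 354, the atrial covariate 267 and the authors' deposited calls 433. The overlap of 225 was 111 without the filter and 59 to 219 when a library was left out, with 68, 59, 108 and 146 without the WT replicate 1, WT replicate 2, NS-DADm replicate 1 or NS-DADm replicate 3 of the NS-DADm experiment. The 30 calls over the authors' themed sheets in NS-DADm hearts were 16 without the filter, 65 with all 12 libraries, 11 with the 3 libraries of low atrial markers and 10 to 23 when a library was left out (11, 10 and 13 without WT replicate 1, WT replicate 2 or NS-DADm replicate 1). Where fewer samples do not account for a change, the cause was not tested.

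Of the lists called with the preset correlation, 28 in KO and 18 in NS-DADm hearts, 0 were called in either with an estimated correlation, where the number of lists with an adjusted p under 0.05 by fry was 47 and 6. Without 1 library 25 to 28 lists were called in KO and 14 to 23 in NS-DADm hearts. Of 264 genes named or listed by the rule and called in KO hearts, 23 lost the call under some setting and 5 without a library. Of 74 in NS-DADm hearts 44 and 39 did, and of 10 for the difference 0 under any setting. With the NS-DADm spread, 21 of the KO genes lost their call, among them Nppa, Myl4 and Sln, whose spread between the NS-DADm libraries was wide.

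The replicate numbers gave no sign of pairing in the KO experiment and left it open in the NS-DADm experiment. Deviations of libraries with the same number correlated at -0.06, -0.02 and 0 in the KO experiment and at 0.01, 0.38 and 0.44 in the NS-DADm experiment. There WT replicates 2 and 3 correlated best with the NS-DADm library of the same number, while WT replicate 1 correlated best with NS-DADm replicate 2 (0.19). Each of these pairs was also alike in atrial markers. Pairs unlike in them reached -0.45 (WT replicate 3, NS-DADm replicate 2) and -0.34 (WT replicate 2, NS-DADm replicate 3). WT replicate 3 and NS-DADm replicate 1, both high, correlated at 0.07. Pairing by number can therefore not be told apart from the difference in atrial markers. With the replicate block KO had 7724 calls, NS-DADm 496, the difference 5501, the overlap 342 and the NS-DADm themed sheets 48. Tests and scalings made for counts (DESeq2, the count test of edgeR, TMM and RLE scaling) were planned for counts and were not run on FPKM. With the observed spread, 64% of simulated 1.5-fold changes were recovered in the NS-DADm experiment and 92% in the KO experiment, with 24% and 56% at the smallest fold simulated. Small changes in NS-DADm hearts can therefore have been missed. Only genes well above the 1 FPKM limit were changed in the simulation, so these shares do not cover genes near it.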

Other observations

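The tests of the Ncor1 region, of an effect shared with HDAC3 loss, of sex, of atrial tissue and of the genotype, and the splits of the libraries for the 2 counts of genes, were chosen only after the results were seen. Genes of muscle protein turnover went both ways in KO hearts. In the list of atrophy genes and ubiquitin ligases Fbxo40, a muscle ubiquitin ligase subunit, rose from 83.6 ± 0.825 to 174.8 ± 3.3 FPKM (SD, n = 3; limma adjusted p = 6.49e-10), and Klhl41, which acts in the upkeep of muscle fibres, fell from 45.2 ± 0.904 to 14.2 ± 0.466 (3.42e-10). Klhl41 also fell in NS-DADm hearts, from 46.4 ± 1.16 to 33.2 ± 1.9 (0.0065). Of the circadian clock list 6 of 19 genes rose and 8 fell in KO hearts (camera adjusted p = 0.267), among the latter Dbp, from 52.6 ± 3.87 to 28.1 ± 0.191, and Per3, from 4.52 ± 0.201 to 2.18 ± 0.245 (limma adjusted p = 1.11e-07 and 7.48e-06). Times of tissue collection were not used here. Among partners and relatives of HDAC3, Tbl1x rose from 11.4 ± 0.33 to 20.6 ± 0.235 and Hdac11 fell from 15.2 ± 1.38 to 6.01 ± 0.125 in KO hearts (1.26e-07 and 8.6e-08).

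By chromosome, NS-DADm calls were fewest for the number tested on chromosome 5 (5 of 738 genes, 0.7% against 2.8% elsewhere, Fisher's exact test, two-sided, adjusted p = 0.00178 over the chromosomes). On the X chromosome they were more frequent. Of 350 tested genes 22 were called (6.3% against 2.6% elsewhere, adjusted p = 0.00272), 2 higher and 20 lower. The median log2 fold change was -0.084 for X-linked and -0.021 for autosomal genes, and 70.3% of X-linked against 55.8% of autosomal genes lay below 0. Xist lay between 15.11 and 20.56 FPKM in all 6 libraries of this experiment.

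NS-DADm calls were more frequent around Ncor1, with an odds ratio of 2.04 within 25 Mb (24 of 467 genes), a window chosen after the others were seen. One hypothesis is DNA of another strain carried along with the mutated locus. It predicts a surplus in every window, which was there within 10, 20 and 25 Mb (odds ratios 2.31, 1.83 and 2.04, one-sided Fisher p = 0.00683, 0.0134 and 0.00183 among 24 combinations of locus, window and comparison) but not within 5 Mb (2 of 97 genes, 0.76). A change that follows loss of HDAC3 function is another, and predicts that these genes move in KO hearts too: 18 of 21 did so in the same direction against 206 of 268 elsewhere (odds ratio 1.81, one-sided p for fewer 0.891). The explanations cannot be told apart, since they may both hold and only 2 of 97 genes were called nearest to the locus.

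The count of 7775 calls in KO hearts might come from replicate libraries that vary little, from sex or from the loss of HDAC3. With the per-gene spread of the NS-DADm experiment, 5854 of the 10889 genes tested in both were still called. With the KO experiment's own spread 7112 were. This argues against the smaller spread as the whole source of the count only if the 3 libraries of each group are separate animals. The labels do not name animals, and the test cannot decide the question for repeat libraries of the same sample. The libraries differ in sex-linked genes, with 4 Y-linked genes called higher in KO and 4 X-linked partners called lower. As sex follows the groups in these libraries, a difference in sex between the KO and WT libraries cannot be told apart from an effect of genotype. Of the 10 splits of the 6 libraries into 3 against 3, 1 gave as many calls, the real one, and the highest of the others was 0, a design too small for a share under 0.05.

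Nppa and other atrial genes differed between the libraries of the NS-DADm experiment, with the mean of the 3 higher libraries up to 17.6-fold that of the others (Mybphl). Of the 10 measured, 9 were higher in WT replicate 3 and NS-DADm replicates 1 and 3 than in every other library. The NS-DADm genotype predicts that they separate the genotypes, which 0 of the 10 did. An unequal share of atrial tissue and a biological difference between single animals cannot be told apart here, since the 3 libraries were picked by the same markers.

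For the 315 NS-DADm gene calls, 1 of the 10 splits gave as many, the real one, and the highest of the others was 44, in the split of WT replicates 1 and 2 and NS-DADm replicate 2 against the libraries with high atrial markers. For lists at the preset correlation, 1 of 10 splits gave as many as the 28 in KO hearts, with 21 in the highest other, and 2 of 10 gave as many as the 18 in NS-DADm hearts, with 19 in the split by atrial markers. These designs are too small for a share under 0.05. The other splits called 13 to 21 lists in the KO experiment, with 0 genes called in each, and 3 to 19 lists in the NS-DADm experiment. A list call at the preset correlation is therefore weak evidence of a genotype effect. Splits that mix the genotypes can keep part of their difference, so these counts do not give a rate of false calls. For the 5348 calls of the difference, 4 of 100 drawn splits gave as many, with a highest other count of 6245. This share comes from a random draw and covers only a grouping of both experiments at once. It does not exclude chance for the grouping of either experiment alone. Of the 100, 10 kept the KO and WT libraries apart as they are, all 4 were among these, and the highest count of the rest was 9, so the count rests on the KO grouping, whose own 10 splits are too few. With that grouping kept, 3 of 9 other NS-DADm groupings gave more calls than the real one. These were the NS-DADm and WT groups exchanged whole (6245), the split by atrial markers (5599), and WT replicate 3 with NS-DADm replicates 2 and 3 against the others (5456). For the NS-DADm grouping chance is therefore not excluded by these splits.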
